A study of Danio rerio with 18 samples.

How the data were processed

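Whole-body RNA of AB wild type zebrafish larvae at 120 hours post fertilisation was sequenced from 18 samples in 6 groups of 3: unexposed controls and larvae exposed to perfluorobutanesulfonic acid (PFBS) at 7, 70, 700, 3500 or 7000 µM. PFBS is a short-chain perfluorinated surfactant, and perfluorooctanesulfonic acid (PFOS) is its longer-chain relative. Per the labels' protocols, RNA was isolated with RNAzol and the libraries were quantified with a KAPA assay before sequencing. The aligner, the counting program, the genome build, the annotation release, the vehicle, the exposure window and the number of larvae per sample are not given in the sources used here. Nothing in the labels says that the samples of a group came from separate animals or pools, so p-values measure the spread between these samples, which may be technical.

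The deposited table held, per the file headers, 1 line for each annotated transcript with its Ensembl identifier, chromosome, start, end, strand and biotype, and the read counts of each sample as whole numbers. Beside the counts the authors deposited RPKM and TPM values, which are scaled for transcript length and library size, and log2 fold changes with p-values, q-values and a yes or no call for each concentration against controls. The deposited counts were used for every test. The deposited TPM values were not used, and the deposited RPKM values served only to derive transcript lengths for a check of length bias. Of 59876 transcripts of 32520 genes, 10033 had no read in any library. Total counts per library ran from 14937147 to 19267232. Strand use and the treatment of reads that match several places were not stated, so values of close paralogs and of overlapping genes are uncertain, as are shares of reads between transcripts of a gene. Coordinates are those of the deposited table.

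Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1; data.table version 1.17.8). Transcripts with too few counts were removed with filterByExpr, which left 31721, and libraries were scaled by the trimmed mean of M values (TMM). All 18 libraries entered a single quasi-likelihood fit with a mean for each group, and contrasts were tested with the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the 31721 transcripts and a threshold of 0.05. The common dispersion was 0.096, a coefficient of variation of 31% between samples of a group. Each concentration was compared with controls, 7000 with 3500 µM and 3500 with 700 µM, and a trend was tested over the order of the 6 groups. Levels are CPM values, counts scaled to library size and TMM factor, as mean ± SD of 3 samples, and fold changes are log2 values ± SE. Where every library of a group had 0 counts, the fold is given against a floor of 3 counts summed over that group. The SE includes the spread between samples as the fit estimated it. Floors, and the upper limit given for a share of 0, cover counting error only.

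Before the data were examined, the samples were assigned to groups, the tests and their alternatives were chosen, and 43 gene lists were fixed, covering the nervous system and eye, lipid and drug metabolism, stress responses, endocrine axes, mitochondria and markers of tissues in a whole larva. A list with under 5 measured genes was not tested, which left 42. Each list was tested with the directional fry test of limma on 1 transcript per gene, the one with the highest mean level, with adjustment over the 42 lists within a comparison. Fry asks whether the genes of a list move on balance in 1 direction, and it does not compare them with other genes. Camera with an estimated correlation between genes and with a preset correlation of 0.01 served as alternatives. Unlike fry, camera compares the genes of a list with the other genes. An adjusted p given below "with an estimated correlation" is from camera, so it differs from that of fry in the question asked as well as in the correlation. Members past the threshold were counted over all transcripts tested and adjusted over the list alone. Genes named for a concentration were chosen by a rule fixed at the same time: among transcripts past the threshold, with a gene name, at least 5 CPM in the higher group and all 3 exposed samples outside the control range, the 10 with the largest rise and the 10 with the largest fall, taken in rank order. The rule added up to 4 members of each called list and every gene of a panel of neurotoxicity markers. Genes named outside the rule are said to be so. A gene symbol stands for 1 transcript, the called one for large changes and the one with the highest mean level for list members. Coordinates tell transcripts of a gene apart where their changes differed.

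The script for the tests was run on simulated counts drawn from the means and library sizes of these samples. For 7000 µM against controls, on 31094 transcripts, it recovered 35 of 50 transcripts raised by a log2 of 1, 38 of 50 lowered by a log2 of 1, 48 of 50 raised by a log2 of 2 and 50 of 50 lowered by a log2 of 2, with 9 false calls. For the trend, on 31038 transcripts, it recovered 42 of 50, 38 of 50, 50 of 50 and 50 of 50 for the same sizes over the full range of groups, with 18 false calls. For 7 µM against controls, on 31087 transcripts, a list raised by a log2 of 0.5 reached an adjusted p of 4.3e-06, and 0 of the other lists were called. Transcripts were drawn independently of each other, so this run does not measure how often fry calls lists of genes that move together between samples.

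The alternatives planned were relative log expression size factors, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in 3 samples, counts summed per gene (21046 genes), an absolute log2 fold change of at least 1, the replicate number as a block, fits on the 2 groups compared, and leaving out each replicate in turn. After the data were seen, leaving out replicate 3 of the 7000 µM group and a fit with the mean of the notochord and epidermis list as a covariate were added, and each sample was left out in turn for the gene lists. That mean was measured after exposure, so the covariate fit also removes any effect of PFBS that moves with it.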

Results

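The study asked whether PFBS disturbs the development of the zebrafish nervous system through mechanisms like those of PFOS. Transcript counts of whole larvae at 120 hours post fertilisation were compared across controls and 5 PFBS concentrations with 3 samples each. Total counts were 18720802, 14937147 and 17114017 in the control samples, 17368885, 19267232 and 17198957 at 7 µM and 15842073, 16877621 and 18263459 at 70 µM. They were 15718868, 19146539 and 16970259 at 700 µM, 17891964, 16040209 and 18656406 at 3500 µM and 17366633, 15991654 and 16984935 at 7000 µM. Samples of a group differed by more than counting noise in each of the 18 pairs. The chi-square per degree of freedom lay between 8.95 and 55.46. None was treated as a repeat of another. Genes that encode proteins of skeletal muscle took 17.72 ± 0.47% of counts in controls (SD, n = 3) and 8.71 ± 3.91% at 7000 µM. There replicate 3 had 4.188% and the other samples 11.03% and 10.904%. Mitochondrial transcripts took 6.48 ± 0.31% in controls and 9.88 ± 1.81% at 7000 µM, with 11.978% in replicate 3. Ribosomal RNA took 0.474% in replicate 3 at 7000 µM and 0.137 to 0.233% in the other libraries, and the transcript zgc:158463 took 1.41% there and 0.136 to 0.704% in the others.

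The first principal component of log2 CPM, with counts summed per gene, held 30.9% of the variance and the second 16%. Replicate 3 of the 7000 µM group lay apart from the other 17 libraries on the first component, at a score of 74.5, against 34.1 and 20 for the other samples of its group. The number of transcripts called against controls was 0 at 7 µM, 18 at 70 µM, 74 at 700 µM, 1039 at 3500 µM and 4510 at 7000 µM. In the authors' deposited table the transcripts with a q-value under 0.05 numbered 95, 181, 1048, 1163 and 3362 at the same concentrations. Those called there, by an unadjusted p under 0.05 and at least a 2-fold change, numbered 564, 904, 1305, 1399 and 2608.

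**Figure D1:**
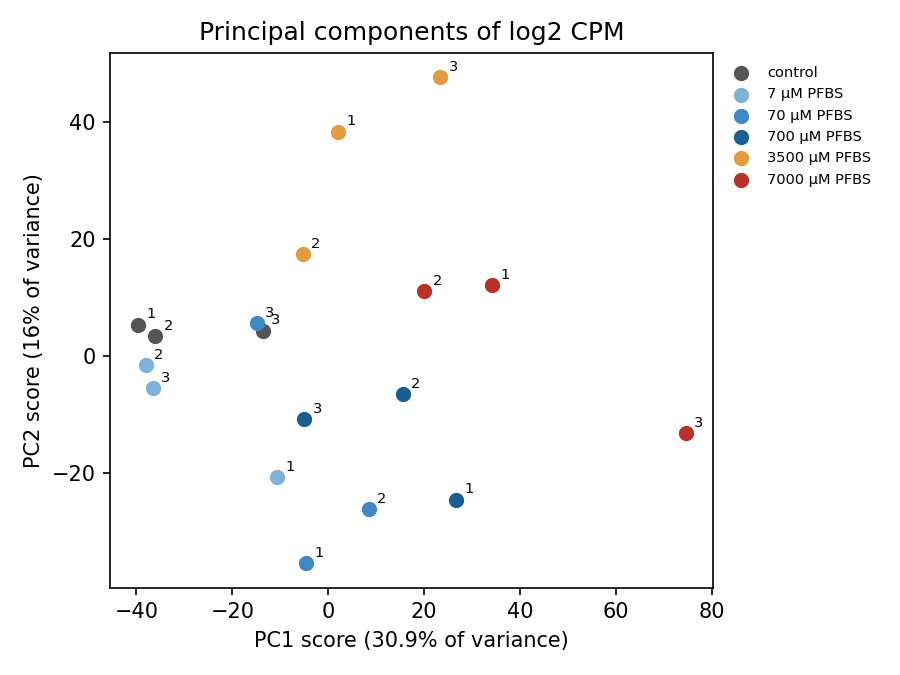
Scores of the 18 libraries on the first (x axis, 30.9% of variance) and second (y axis, 16% of variance) principal components of log2 CPM of counts summed per gene, coloured by PFBS concentration and numbered by replicate. Replicate 3 at 7000 µM sits at a first-component score of 74.5, beyond every other library.

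**Figure D2:**
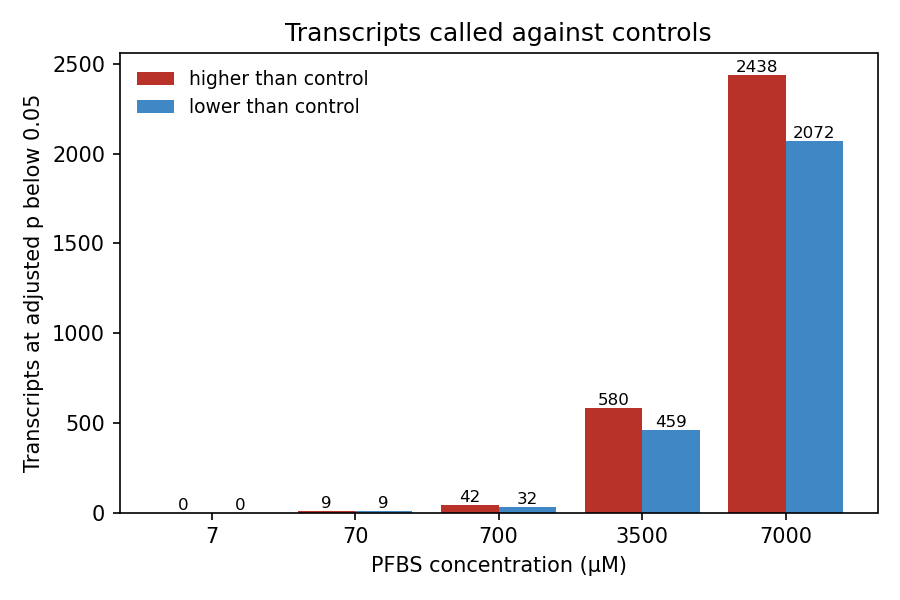
Transcripts higher (red) and lower (blue) than in controls at an edgeR adjusted p below 0.05, on the y axis, for each PFBS concentration on the x axis (µM, 3 samples against 3). The bars rise from 0 at 7 µM to 2438 higher and 2072 lower at 7000 µM.

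The comparison at 7 µM asked whether the lowest concentration changed the transcriptome. Genes of cholesterol synthesis rose as a group, with a median log2 fold change of 0.52 over 29 measured genes (fry adjusted p = 0.00012; adjusted p = 0.00028 with an estimated correlation). The list mean was 0.49, 0.48 and 0.47 above the control mean in the 3 samples. Of these genes 0 passed over all transcripts and 16 were higher and 0 lower when adjusted over the list alone. The 30 genes of fatty acid and triglyceride synthesis rose as well (median 0.1, adjusted p = 0.0022; adjusted p = 0.0037 with an estimated correlation). Past the threshold were 0 over all transcripts and 4 higher adjusted over the list alone. The 37 lipid genes linked to PPAR, the nuclear receptors that sense fatty acids, had a median of 0.34 (adjusted p = 0.03; adjusted p = 0.024 with an estimated correlation). Past the threshold were 0 over all transcripts and 3 higher adjusted over the list alone. Neutrophil and macrophage genes fell (42 genes, median -0.4, adjusted p = 0.032; adjusted p = 0.038 with an estimated correlation). Past the threshold were 0 over all transcripts and 2 lower adjusted over the list alone.

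No transcript passed the adjusted threshold at 7 µM in edgeR's test, and 1346 had an unadjusted p below 0.05 where 1586 are expected by chance. DESeq2 called 75 transcripts and edgeR on counts summed per gene called 7 genes. A pair of transcripts that were called at higher concentrations, chosen here after their values were seen, showed the same signs: apoeb stood at 68.9, 93.2 and 75.3 CPM against 157, 172 and 152 CPM in controls (log2 fold change -1.02, adjusted p = 0.0744), and insig1 had a log2 fold change of 0.56 (adjusted p = 0.107). The calls of the PPAR-linked list and of the neutrophil and macrophage list were lost without any 1 of control replicates 1, 2 or 3 or of 7 µM replicates 1 or 2, with adjusted p from 0.055 to 0.13 and from 0.06 to 0.22.

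At 70 µM, 9 transcripts rose and 9 fell, from 17 genes. The rises were led by enzymes of lipid synthesis. The fatty acid desaturase fads2 (chromosome 25, 4133489 to 4148719) went from 3.45 ± 0.891 to 14.3 ± 7.52 CPM (n = 3 each, log2 fold change 2.05 ± 0.31, adjusted p = 0.044). The enzyme elovl2, which elongates polyunsaturated fatty acids (chromosome 24, 8861272 to 8887825), was 2.42-fold higher. Squalene epoxidase sqlea (chromosome 16, 43401005 to 43413293) and lanosterol demethylase cyp51 (chromosome 19, 598657 to 617246) were each 2.4-fold higher, with log2 changes of 1.26 ± 0.21 and 1.26 ± 0.2. The sterol-regulated membrane protein insig1 (chromosome 7, 41007773 to 41014773) rose from 20.1 ± 0.705 to 33.7 ± 1.4 CPM (0.75 ± 0.09, adjusted p = 0.0087). The uncoupling protein transcript ucp2 (chromosome 10, 36667996 to 36668878), the ERK phosphatase dusp5 and the cryptochrome cry1b rose 2.36-, 2.26- and 1.43-fold.

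The falls at 70 µM were led by lgals1l1, which encodes a galectin (chromosome 3, 28939759 to 28946756), at 24.2 ± 5 CPM against 77.1 ± 9.09 CPM in controls (-1.67 ± 0.27, adjusted p = 0.044). The apolipoprotein E gene transcript apoeb (chromosome 16, 23960744 to 23963461) stood at 69.1 ± 9.55 against 161 ± 10.5 CPM (-1.22 ± 0.14, adjusted p = 0.0087). Another galectin, lgals9l1, the integrin itgae.1 and the transcriptional repressor bcl6ab were 2.27-, 1.94- and 1.81-fold lower.

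Among the lists at 70 µM, cholesterol synthesis had 4 members higher and 0 lower over all transcripts and 18 higher and 0 lower adjusted over the list alone (median 0.53, fry adjusted p = 1.7e-05; adjusted p = 0.00033 with an estimated correlation). Lanosterol synthase lss stood at 1.18 ± 0.16. Fatty acid and triglyceride synthesis had 2 higher over all transcripts and 5 higher adjusted over the list alone (median 0.17, adjusted p = 0.001; adjusted p = 0.0083 with an estimated correlation). Neutrophil and macrophage genes had 0 past the threshold over all transcripts and 10 lower adjusted over the list alone (median -0.6, adjusted p = 0.0013; adjusted p = 0.011 with an estimated correlation). The notochord and epidermis list, a marker list of the body wall, stood at -1.03, -1.03 and -0.2 in the 3 samples of this group and was not called. The 45 hypoxia and glycolysis genes had a median of 0.12 (adjusted p = 0.0078; adjusted p = 0.057 with an estimated correlation). Past the threshold were 0 over all transcripts and 1 higher adjusted over the list alone. The 45 circadian clock genes had a median of 0.3 (adjusted p = 0.041; adjusted p = 0.13 with an estimated correlation). Past the threshold were 1 higher over all transcripts and 10 higher adjusted over the list alone.

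The count at 70 µM was 2, 10 and 4 without control replicates 1, 2 and 3, and 1 and 4 without 70 µM replicates 1 and 2. The circadian call was lost without any 1 of the control replicates or of 70 µM replicates 1 or 2, with adjusted p from 0.073 to 0.17, and with the notochord and epidermis mean as a covariate (median 0.18, adjusted p = 0.28). Of the 14 calls of named transcripts, 1, 4 and 7 were kept without 70 µM replicates 1, 2 and 3.

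At 700 µM, 42 transcripts rose and 32 fell. The largest rise among the named transcripts was that of cyp2k18, which encodes a cytochrome P450 of family 2 (chromosome 3, 12710350 to 12715432), from 3.83, 4.6 and 2.73 CPM in the controls to 22.5, 24.2 and 41 CPM (n = 3 each, log2 fold change 2.98 ± 0.35, 7.87-fold, adjusted p = 0.0033). The desaturase fads2 was 3.55-fold higher, the elongase elovl2 2.94-fold, cyp51 2.67-fold and dusp5 2.38-fold. The glucocorticoid-responsive co-chaperone gene transcript fkbp5 rose from 40.8 ± 14.6 to 124 ± 5 CPM (1.6 ± 0.31, adjusted p = 0.0499). The photoreceptor transcripts guca1c and guca1b, activators of retinal guanylate cyclase, were 2.12- and 2.01-fold higher. The rod transducin subunit gnat1 went from 170 ± 14 to 316 ± 35.6 CPM (0.89 ± 0.16, adjusted p = 0.047). Rhodopsin, rho (chromosome 8, 54076195 to 54077740), went from 2550 ± 89.4 to 4180 ± 326 CPM (0.71 ± 0.13, adjusted p = 0.047).

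The falls at 700 µM included tdh (chromosome 20, 18994059 to 18996866), of the threonine dehydrogenase gene, which was 5.7-fold lower (-2.51 ± 0.47, adjusted p = 0.048) while the counts of its gene summed over transcripts had a log2 change of -0.52. The small heat shock gene transcript hspb1 stood at 9.73 ± 1.47 CPM against 32.5 ± 18 CPM in controls (-1.74 ± 0.33, adjusted p = 0.048). The galectin lgals1l1 was 2.85-fold lower and apoeb was 2.59-fold lower, at 62.1 ± 8.55 CPM (-1.37 ± 0.14, adjusted p = 0.0033). The myosin myo9b, the actin branching subunit arpc1b and the lysosomal sulfatase gnsb were 2.41-, 2.34- and 2.32-fold lower.

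Of 42 lists, 10 rose and 3 fell at 700 µM. Cholesterol synthesis had 6 members higher over all transcripts and 18 higher adjusted over the list alone (median 0.52, fry adjusted p = 9.4e-06; adjusted p = 0.00075 with an estimated correlation). Fatty acid and triglyceride synthesis had 2 higher over all transcripts and 13 higher and 2 lower adjusted over the list alone (median 0.25, adjusted p = 0.0002; adjusted p = 0.0069 with an estimated correlation). Hypoxia and glycolysis had 1 higher over all transcripts, pgam1a of glycolysis at 0.54 ± 0.1, and 5 higher adjusted over the list alone (median 0.24, adjusted p = 0.00068; adjusted p = 0.019 with an estimated correlation). Neutrophil and macrophage genes had 0 over all transcripts and 11 lower adjusted over the list alone (median -0.61, adjusted p = 0.00068; adjusted p = 0.019 with an estimated correlation).

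Of 61 phototransduction and photoreceptor genes at 700 µM, 6 were higher over all transcripts and 41 higher adjusted over the list alone (median 0.51, adjusted p = 0.02; adjusted p = 0.12 with an estimated correlation). The list means were 0.63, 0.5 and 0.33 in the 3 samples, whose notochord and epidermis means were -1.35, -0.94 and -0.54. The latter list had 0 members higher and 1 lower over all transcripts and 33 lower of 46 adjusted over the list alone (median -0.94, adjusted p = 0.047; adjusted p = 0.18 with an estimated correlation). The 60 genes of inflammation and the acute phase had 0 past the threshold over all transcripts and 16 lower adjusted over the list alone (median -0.62, adjusted p = 0.02; adjusted p = 0.14 with an estimated correlation).

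Smaller list medians were called at 700 µM for PPAR-linked genes (0.25, adjusted p = 0.019; 1 higher over all transcripts, 4 adjusted over the list alone), heat shock (0.16, adjusted p = 0.037; 2 higher and 1 lower, 6 higher and 1 lower adjusted over the list alone) and retinoid metabolism (0.17, adjusted p = 0.037; 1 higher, 3 higher and 1 lower adjusted over the list alone). The last includes the retinoic acid hydroxylase cyp26a1 at 0.82 ± 0.13. The unfolded protein and integrated stress response list (0.08, adjusted p = 0.047) had 1 member higher over all transcripts and 3 adjusted over the list alone. The circadian clock list (0.24, adjusted p = 0.049) had 0 and then 12 higher and 1 lower, and the cell cycle and DNA replication list (0.15, adjusted p = 0.049) had 0 and then 1 higher. With an estimated correlation these 6 lists had adjusted p of 0.11, 0.17, 0.17, 0.21, 0.21 and 0.3 in the order named.

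The count at 700 µM was 6, 14 and 30 without control replicates 1, 2 and 3, and 9, 10 and 21 without 700 µM replicates 1, 2 and 3. It was 241 without 7000 µM replicate 3, which enters through the shared spread. List calls lost without any 1 of the 6 libraries were those of cell cycle (adjusted p from 0.067 to 0.23), circadian clock (0.095 to 0.14) and notochord and epidermis (0.053 to 0.15). Those of heat shock (0.072 to 0.19) and unfolded protein (0.1 to 0.23) held only without control replicate 1, and that of retinoid metabolism (0.072 to 0.12) only without control replicate 2. The call of phototransduction was lost without control replicates 1 or 3 or 700 µM replicates 1 or 2 (0.053 to 0.072). The call of inflammation was lost without control or 700 µM replicates 1 or 2 (0.072 to 0.095), and that of PPAR-linked genes without control or 700 µM replicate 3 (0.057 to 0.067). Of the 30 calls of named transcripts at 700 µM, 5, 5 and 9 were kept without 700 µM replicates 1, 2 and 3.

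With the notochord and epidermis mean as a covariate, added after the data were seen, 6 of the 13 lists called at 700 µM were kept and 7 were not. The phototransduction median went from 0.51 to 0.13 (adjusted p = 0.25), that of inflammation from -0.62 to -0.34 (0.25) and that of the circadian clock from 0.24 to 0.12 (0.48). The notochord and epidermis list itself went to 0.06 (0.37). Those of PPAR-linked genes, retinoid metabolism and cell cycle were 0.2, 0.14 and 0.17 (0.052, 0.21 and 0.15). Neutrophil and macrophage genes were kept at -0.37 (0.015).

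At 3500 µM, 580 transcripts rose and 459 fell, and 327 changed at least 2-fold. The cytochrome P450 transcript cyp2k18 was 12.4-fold higher, at 46 ± 4.51 CPM (n = 3, log2 fold change 3.63 ± 0.35, adjusted p = 0.00027). The immediate early transcript ier2b (chromosome 11, 31038409 to 31039533) rose from 20.1 ± 1.06 to 137 ± 73.4 CPM (2.76 ± 0.32, adjusted p = 0.00087). The AP-1 subunit fosab (chromosome 20, 46552311 to 46554440) rose from 67.8 ± 4.33 to 451 ± 292 CPM (2.73 ± 0.44, adjusted p = 0.0049). The nuclear receptor nr4a3 and the antiproliferative gene transcript btg2 were 4.08- and 4.04-fold higher, and the call of nr4a3 was lost without any 1 of 4 of the 6 libraries (adjusted p up to 0.14). The co-chaperone fkbp5, the small heat shock protein hspb9 and fads2 were 4.89-, 4.56- and 4.44-fold higher. The transcript mapk6 (chromosome 18, 39170127 to 39288894) was 4.28-fold higher with a log2 change of 0.32 for its gene summed over transcripts, and plac8.1 was 4.19-fold higher.

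Among the named falls at 3500 µM were transcripts of plasma proteins made by the liver. The antitrypsin-like serpina1l (chromosome 20, 10538025 to 10541197) stood at 1.6 ± 0.727 CPM against 10.6 ± 4.46 CPM in controls (-2.71 ± 0.56, adjusted p = 0.019). The inhibitor chain itih3a, the vitamin D binding protein gc, the pentraxin crp2, complement c3a.2 and the carboxylesterase ces3 were 5.48-, 5.48-, 5.09-, 4.47- and 4.43-fold lower. With each of the 6 libraries left out in turn, the call of gc was lost 4 times and those of serpina1l and ces3 3 times. Those of crp2 and c3a.2 were lost 2 times and that of itih3a 1 time (adjusted p up to 0.11, for gc). The hepatocyte and lipoprotein list itself was not called (50 genes, median -1.11, adjusted p = 0.097). It had 9 members lower and 0 higher over all transcripts and 24 lower and 2 higher adjusted over the list alone. The transcripts rlf (chromosome 17, 24597001 to 24602317) and st6gal2a (chromosome 9, 6079528 to 6123800) had 0 counts in all 3 samples and were at least 201-fold and 96.1-fold lower than in controls. Their genes summed over transcripts had log2 changes of -0.1 and -0.25. The call of st6gal2a was lost without any 1 of the 6 libraries (adjusted p up to 0.15), and that of rlf was lost without 0 of them. The neuronal RNA-binding gene transcript elavl4 (chromosome 8, 16004154 to 16112401) was 4.9-fold lower, with a log2 change of -0.21 for its gene, and lost its call without 5 of the 6 libraries in turn (adjusted p up to 0.12).

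Of 42 lists, 14 rose and 1 fell at 3500 µM. Cholesterol synthesis had 8 members higher and 0 lower over all transcripts and 17 higher and 0 lower adjusted over the list alone (median 0.49, fry adjusted p = 2e-05; adjusted p = 0.0049 with an estimated correlation). Its member with the smallest adjusted p was insig1, which rose 1.99-fold to 40 ± 5.33 CPM (0.99 ± 0.09, adjusted p = 0.00023). Fatty acid and triglyceride synthesis had 6 higher and 1 lower over all transcripts and 9 higher and 1 lower adjusted over the list alone (median 0.18, adjusted p = 3.9e-05; adjusted p = 0.0054 with an estimated correlation). PPAR-linked genes had 7 higher and 0 lower over all transcripts and 9 higher adjusted over the list alone (median 0.17, adjusted p = 0.0011; adjusted p = 0.029 with an estimated correlation). The lipase inhibitor angptl4 stood at 1.08 ± 0.14 and ucp2 (chromosome 10, 36662640 to 36673388) at 1.06 ± 0.14. The related ucp3 went from 19.2 ± 1.08 to 71.3 ± 12.3 CPM (1.89 ± 0.3, adjusted p = 0.0047). Fatty acid oxidation had 3 higher over all transcripts and 13 higher and 1 lower adjusted over the list alone (39 genes, median 0.17, adjusted p = 0.04; adjusted p = 0.31 with an estimated correlation). The carrier cpt1ab, which brings fatty acids into mitochondria, stood at 0.52 ± 0.1.

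Stress lists rose at 3500 µM. The unfolded protein and integrated stress response list had 9 members higher and 0 lower over all transcripts and 13 higher adjusted over the list alone (median 0.08, adjusted p = 0.00029; adjusted p = 0.021 with an estimated correlation). The ATF4 targets chac1 and trib3 stood at 0.89 ± 0.11 and 0.7 ± 0.09. Heat shock had 7 higher and 1 lower over all transcripts and 13 higher and 1 lower adjusted over the list alone (median 0.21, adjusted p = 0.00067; adjusted p = 0.026 with an estimated correlation). The inducible hsp70l stood at 64.4 ± 22.6 against 22.5 ± 3.56 CPM. Hypoxia and glycolysis had 7 higher and 1 lower over all transcripts and 16 higher and 1 lower adjusted over the list alone (median 0.27, adjusted p = 2.2e-05; adjusted p = 0.0049 with an estimated correlation). The angiogenic factor vegfaa stood at 0.77 ± 0.12. The p53 and apoptosis list had 8 higher and 0 lower over all transcripts and 13 higher and 3 lower adjusted over the list alone (median 0.23, adjusted p = 0.0011; adjusted p = 0.033 with an estimated correlation). Its member gadd45aa stood at 1.15 ± 0.19. The stress axis and glucocorticoid response list had 5 higher over all transcripts and 13 higher of 22 adjusted over the list alone (median 0.6, adjusted p = 0.0011; adjusted p = 0.029 with an estimated correlation). The glucocorticoid-induced tsc22d3 stood at 0.81 ± 0.15. Nrf2 and oxidative stress had 3 higher over all transcripts and 3 adjusted over the list alone (38 genes, median 0.14, adjusted p = 0.0055; adjusted p = 0.14 with an estimated correlation). Glutathione peroxidase gpx1b was 3.09-fold higher.

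All 13 measured mitochondrially encoded genes were higher adjusted over the list alone at 3500 µM, and 10 over all transcripts (median 0.58, adjusted p = 0.0023; adjusted p = 0.063 with an estimated correlation). Of these mt-nd2 stood at 4380 ± 589 against 2650 ± 127 CPM. Of 85 nuclear genes of oxidative phosphorylation, 13 were higher and 0 lower over all transcripts and 53 higher adjusted over the list alone (median 0.32, adjusted p = 0.01; adjusted p = 0.19 with an estimated correlation). Cytochrome c, cycsb, stood at 0.74 ± 0.12. Neutrophil and macrophage genes had 1 lower over all transcripts, the actin-bundling lcp1 at -0.98 ± 0.24, and 3 lower adjusted over the list alone (median -0.34, adjusted p = 0.016; adjusted p = 0.29 with an estimated correlation). Retinoid metabolism had 1 higher over all transcripts and 2 higher and 1 lower adjusted over the list alone (median 0.12, adjusted p = 0.041; adjusted p = 0.25 with an estimated correlation).

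The 3500 µM count was 219, 228 and 650 without control replicates 1, 2 and 3, 336 and 319 without 3500 µM replicates 1 and 3, and 2806 without 3500 µM replicate 2. The call of fatty acid oxidation held only without 3500 µM replicate 2 (adjusted p otherwise 0.076 to 0.13). The call of retinoid metabolism was lost without control or 3500 µM replicates 1 or 3 (0.083 to 0.17), and that of neutrophils and macrophages without control replicate 1 or 3500 µM replicate 2 (0.053 to 0.059). Of the 64 calls of named transcripts, 45, 60 and 40 were kept without 3500 µM replicates 1, 2 and 3. With the notochord and epidermis mean as a covariate all 15 list calls at 3500 µM were kept. That mean was near the controls in this group (-0.12, -0.18 and -0.22 against 0.14, 0.01 and -0.15), so adjusting for it could change these medians little.

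At 7000 µM, 2438 transcripts rose and 2072 fell, and with relative log expression size factors 2644 and 1908 did. Of the former, 364 rose and 1033 fell at least 2-fold. The clearest single rise of a whole gene among the named transcripts was that of arf4b, which encodes a small GTPase of the Golgi (chromosome 11, 42466834 to 42472941), from 0.367 ± 0.149 to 18.6 ± 3.71 CPM (n = 3 each, 48.8-fold, log2 fold change 5.61 ± 0.29, adjusted p = 2.3e-07). Other large changes were of single transcripts. The microtubule gene transcript map1aa (chromosome 7, 52830254 to 52842605), the potassium channel partner dpp6b (chromosome 2, 12406714 to 12502495), chid1 (chromosome 25, 3788443 to 3800888) and e2f4 (chromosome 25, 17405458 to 17419095) had 0 counts in all 3 controls. They were at least 281-, 158-, 112- and 104-fold higher, while their genes summed over transcripts had log2 changes of -0.2, 0.52, 0.47 and 0.01. The muscle troponin transcript tnnt3b (chromosome 7, 39446247 to 39460048) went from 169 ± 103 CPM to 0 counts, at least 2990-fold lower, with a log2 change of -0.93 for its gene. The mitochondrial porin transcript vdac2 (chromosome 13, 17714446 to 17723417), the keratin krt5 (chromosome 23, 10174394 to 10175898), the cadherin cdh2 (chromosome 20, 17783404 to 17817458) and the lactate dehydrogenase ldha (chromosome 25, 25124684 to 25130698) were at least 1500-, 1080-, 230- and 124-fold lower, with gene sums at -0.47, -1.42, -0.14 and 0.35. With each of the 6 libraries left out in turn, the calls of e2f4 and ldha were lost 6 times (adjusted p up to 0.12 and 0.14) and those of vdac2 and krt5 5 times (up to 0.088 and 0.087). Those of map1aa and cdh2 were lost 3 and 2 times (up to 0.074 and 0.069), and those of dpp6b, chid1 and tnnt3b 0 times.

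Lipid synthesis genes rose at 7000 µM. Cholesterol synthesis had 17 members higher and 0 lower over all transcripts and 20 higher and 0 lower adjusted over the list alone (median 0.62, fry adjusted p = 1.6e-06; adjusted p = 0.0042 with an estimated correlation). The sterol pathway enzymes hmgcs1, at 62.5 ± 7.51 against 29.9 ± 0.358 CPM (1.07 ± 0.12), cyp51 (1.46 ± 0.2) and hmgcra (0.93 ± 0.14) were among them, with adjusted p of 0.00026, 0.001 and 0.0017. Fatty acid and triglyceride synthesis had 12 higher and 0 lower over all transcripts and 14 higher and 1 lower adjusted over the list alone (median 0.24, adjusted p = 4e-05; adjusted p = 0.023 with an estimated correlation). The desaturase fads2 was 4.15-fold and fatty acid synthase fasn 1.51-fold higher. PPAR-linked genes had 4 higher and 1 lower over all transcripts and 3 higher and 1 lower adjusted over the list alone (median 0.23, adjusted p = 0.008; adjusted p = 0.26 with an estimated correlation). The one that fell was the receptor gene transcript pparg itself, 3.1-fold lower (-1.63 ± 0.38, adjusted p = 0.013; 0.062 without replicate 3).

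Hypoxia and glycolysis had 24 members higher and 1 lower over all transcripts and 27 higher and 4 lower adjusted over the list alone (median 0.41, adjusted p = 1.6e-06; adjusted p = 0.0042 with an estimated correlation). The transcript ndrg1b stood at 120 ± 46.8 against 39.5 ± 0.725 CPM (1.6 ± 0.23) and the glucose transporter slc2a3a at 1.18 ± 0.2. The unfolded protein and integrated stress response list had 14 higher and 2 lower over all transcripts and 21 higher and 2 lower adjusted over the list alone (median 0.23, adjusted p = 2.2e-05; adjusted p = 0.018 with an estimated correlation). The transcription factors atf5b and xbp1 stood at 0.54 ± 0.07 and 0.48 ± 0.08. Heat shock had 15 higher and 1 lower over all transcripts and 16 higher and 2 lower adjusted over the list alone (median 0.24, adjusted p = 0.00038; adjusted p = 0.068 with an estimated correlation). Within it hsp90aa1.2 rose from 111 ± 4.34 to 220 ± 16.8 CPM (0.98 ± 0.08, adjusted p = 3.1e-05) and hsp70l 3.08-fold, and hspb1 was 4.73-fold lower. The glucocorticoid list had 5 higher over all transcripts and 5 adjusted over the list alone (median 0.32, adjusted p = 0.007; adjusted p = 0.26 with an estimated correlation). The corticotropin-releasing hormone binding protein crhbp was 1.92-fold higher. All 13 mitochondrially encoded genes were higher both over all transcripts and adjusted over the list alone (median 0.58, adjusted p = 0.0024; adjusted p = 0.22 with an estimated correlation). Their list mean was 0.85 in replicate 3 against 0.51 and 0.47 in the other samples. Cell cycle and DNA replication genes fell, with 24 lower and 0 higher over all transcripts and 27 lower adjusted over the list alone (66 genes, median -0.24, adjusted p = 0.0019; adjusted p = 0.26 with an estimated correlation). The condensin smc2 stood at -0.63 ± 0.08.

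Photoreceptor genes were higher and muscle and epidermal genes lower at 7000 µM. Of 61 phototransduction and photoreceptor genes, 45 were higher and 0 lower over all transcripts and 54 higher adjusted over the list alone (median 0.77, adjusted p = 0.0019; adjusted p = 0.16 with an estimated correlation). The rod phosphodiesterase subunit pde6ga stood at 90.2 ± 19 against 27.6 ± 1.55 CPM (1.71 ± 0.2, adjusted p = 0.00035). The list mean was 1.01 in replicate 3 and 0.61 and 0.46 in the other samples. Retinoid metabolism, which includes visual cycle genes such as rlbp1b (0.89 ± 0.16), had 10 higher and 1 lower over all transcripts and 11 higher and 4 lower adjusted over the list alone (median 0.17, adjusted p = 0.013; adjusted p = 0.26 with an estimated correlation).

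Of 90 skeletal muscle genes, 43 were lower and 2 higher over all transcripts and 60 lower and 3 higher adjusted over the list alone (median -0.96, adjusted p = 0.013; adjusted p = 0.33 with an estimated correlation). AMP deaminase ampd1 stood at 391 ± 152 against 1150 ± 65.3 CPM and the calcium release channel ryr1b at 58.3 ± 16.2 against 156 ± 30.4 CPM. The muscle list mean was -1.86 in replicate 3 against -0.66 and -0.61 in the other samples. Of 46 notochord and epidermis genes, 22 were lower and 0 higher over all transcripts and 33 lower adjusted over the list alone (median -1.06, adjusted p = 0.017; adjusted p = 0.36 with an estimated correlation). Keratin krt92 was 2.12-fold lower. The list means were -1.88 in replicate 3 and -0.83 and -0.78 in the others. Erythrocyte genes had 9 lower and 0 higher of 35 over all transcripts and 18 lower adjusted over the list alone (median -0.69, adjusted p = 0.017; adjusted p = 0.41 with an estimated correlation). The spectrin sptb was 4.61-fold lower. The list means were -0.77 in replicate 3 and -0.65 and -0.41 in the others. Neutrophil and macrophage genes had 7 lower and 0 higher over all transcripts and 9 lower adjusted over the list alone (median -0.5, adjusted p = 0.0052; adjusted p = 0.33 with an estimated correlation). The scavenger receptor marco was 3.57-fold lower.

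The count at 7000 µM was 1588 without 7000 µM replicate 3, 1530 of them shared with the full set. It was 1623 and 2130 without control replicates 1 and 2, and 1978 with only the 2 groups compared in the fit. Without 7000 µM replicate 3 the muscle, epidermis and erythrocyte lists were not called (medians -0.6, -0.78 and -0.54, adjusted p = 0.069, 0.092 and 0.092), and the photoreceptor list kept a median of 0.61 (adjusted p = 0.0022). The call of the epidermis list was also lost without control replicate 1, and that of the erythrocyte list without 7000 µM replicate 1 or control replicates 1 or 2, with adjusted p from 0.06 to 0.092.

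With the notochord and epidermis mean as a covariate, 137 transcripts were called at 7000 µM, 119 higher and 18 lower. Of the 15 lists called at 7000 µM, 6 were kept and 9 were not. The medians of muscle and erythrocyte genes went from -0.96 to 0.01 and from -0.69 to -0.08 (adjusted p = 0.97 and 0.85), and that of neutrophils and macrophages from -0.5 to -0.08 (0.55). Within groups the erythrocyte list followed the notochord and epidermis mean (Pearson r = 0.83, permutation p = 0.00052, 0.0054 adjusted over 41 lists; Spearman rho = 0.88, permutation p = 0.00043, adjusted 0.0044; r = 0.83 without the 2 farthest samples). The photoreceptor median went from 0.77 to 0.33 (0.052) and that of mitochondrially encoded genes from 0.58 to 0.36 (0.1). PPAR-linked genes, retinoid metabolism and the glucocorticoid list went from 0.23, 0.17 and 0.32 to 0.14, 0.08 and 0.26 (0.052, 0.13 and 0.1). The notochord and epidermis list turned upward (fry adjusted p = 0.008). Its own mean was the covariate, so its value in this fit is not read as a result.

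**Figure D3:**
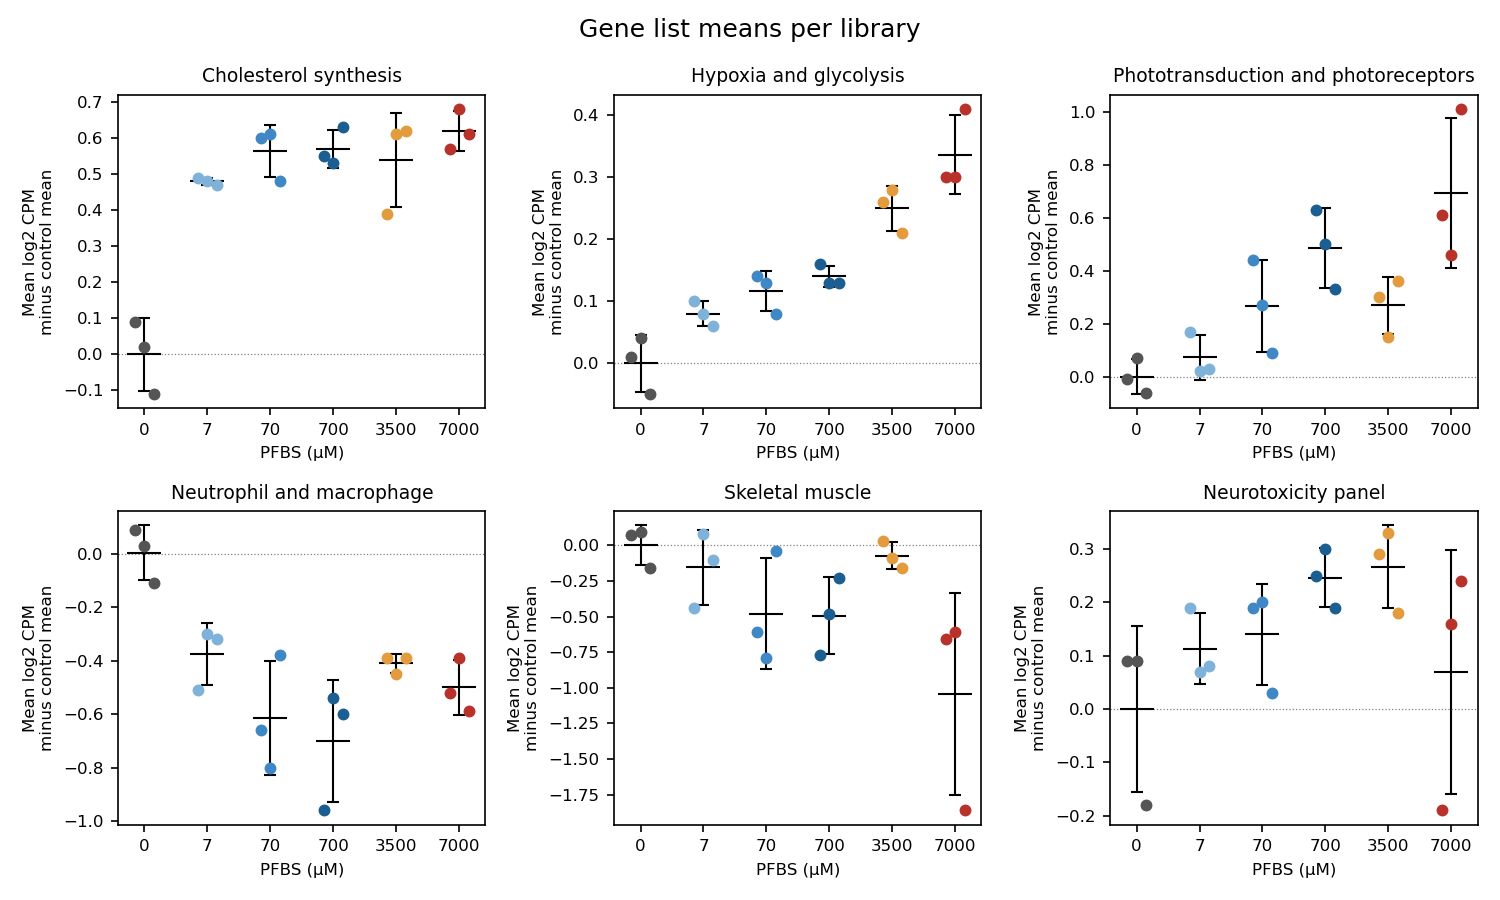
Mean log2 CPM of 6 gene lists in each library minus the mean of controls (y axis) against PFBS concentration in µM (x axis, evenly spaced groups, 0 for controls). Points are libraries and bars are mean ± SD of 3. The cholesterol synthesis means of exposed libraries lie between 0.39 and 0.68, above all 3 controls, while the muscle mean of replicate 3 at 7000 µM is -1.86.

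The nervous system was the subject of the study. The panel of 14 neurotoxicity markers rose at 3500 µM (median 0.22, fry adjusted p = 0.049; adjusted p = 0.31 with an estimated correlation). Of its members 1 was higher and 1 lower over all transcripts, and 2 were higher and 2 lower adjusted over the list alone. This call was lost without any 1 of the 6 libraries but control replicate 3 (adjusted p from 0.067 to 0.26). At the other concentrations the panel was not called, and its direct tests gave adjusted p of 0.91 for 3500 against 700 µM and 0.49 for 7000 against 3500 µM. Its members past the threshold at 3500 µM were the neurotrophin transcript bdnf (chromosome 7, 31924983 to 31932723), at 24.6 ± 3.84 against 12 ± 2.67 CPM (n = 3 each, 1.04 ± 0.17, adjusted p = 0.0064), and the hedgehog mediator gli2b, at -0.58 ± 0.15 (adjusted p = 0.049). With each of the 6 libraries left out in turn the call of gli2b was lost 5 times (adjusted p up to 0.2) and that of bdnf 0 times.

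At 7000 µM the panel had 3 members higher and 3 lower over all transcripts and 5 higher and 4 lower adjusted over the list alone (median 0.29, adjusted p = 0.19). Brain-derived neurotrophic factor, bdnf, was 2.22-fold higher at 26.4 ± 4.86 CPM (1.15 ± 0.17, adjusted p = 0.0017). The transcript nrxn1a of presynaptic neurexin rose by 0.59 ± 0.19 (adjusted p = 0.048) and myelin basic protein, mbpa, by 0.39 ± 0.11 (adjusted p = 0.032). The astroglial filament transcript gfap (chromosome 3, 31792441 to 31804481) fell from 172 ± 29.7 to 90.1 ± 14 CPM (-0.93 ± 0.2, adjusted p = 0.0096). The tubulin tuba1b was 1.7-fold lower (-0.76 ± 0.17, adjusted p = 0.012) and gli2b 1.49-fold lower (-0.57 ± 0.15, adjusted p = 0.021). Acetylcholinesterase, ache, had a log2 change of -0.3 ± 0.1 (adjusted p = 0.054). The markers elavl3, syn2a, gap43, shha, manf, neurog1 and nkx2.2a did not pass, with log2 changes of -0.07, 0.27, 0.19, 0.31, 0.32, 0.5 and 0.4. Without 7000 µM replicate 3 the adjusted p of bdnf and tuba1b were 0.0077 and 0.046, and those of gfap, nrxn1a, mbpa and gli2b were 0.059, 0.2, 0.073 and 0.1. The panel median was -0.05 with the notochord and epidermis mean as a covariate (fry adjusted p = 0.98). Within groups the panel mean had r = -0.48 with that mean (permutation p = 0.21, adjusted 0.34).

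The other neural lists were not called at any concentration. At 7000 µM neuron and synapse genes had 16 higher and 6 lower of 55 over all transcripts and 19 higher and 8 lower adjusted over the list alone (median 0.15, adjusted p = 0.19). Neurotransmitter genes had 15 higher and 1 lower of 51 and 16 higher and 4 lower (median 0.19, adjusted p = 0.051), and neural progenitor genes 7 higher and 0 lower of 28 in both counts (median 0.23, adjusted p = 0.051). Glia and myelin genes had 5 higher and 3 lower of 29, and 5 higher and 4 lower adjusted over the list alone (median -0.19, adjusted p = 0.92). Voltage-gated channel and calcium genes had 9 higher and 8 lower of 54, and 14 higher and 12 lower adjusted over the list alone. Their median was 0.11 and their mean -0.15, with an upward test direction (adjusted p = 0.59). Within groups, the neuron and synapse mean went against the notochord and epidermis mean (Pearson r = -0.59, permutation p = 0.0051, adjusted 0.019). The other neural lists had adjusted p of 0.054 or more. Medians at 7000 µM with the notochord and epidermis mean as a covariate were -0.04, 0.01, 0.07, 0.07 and -0.09 in the order named. Their fry adjusted p were 0.81, 0.81, 0.75, 0.26 and 0.26. That fit also removes any effect of PFBS that moves with that mean.

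**Figure D4:**
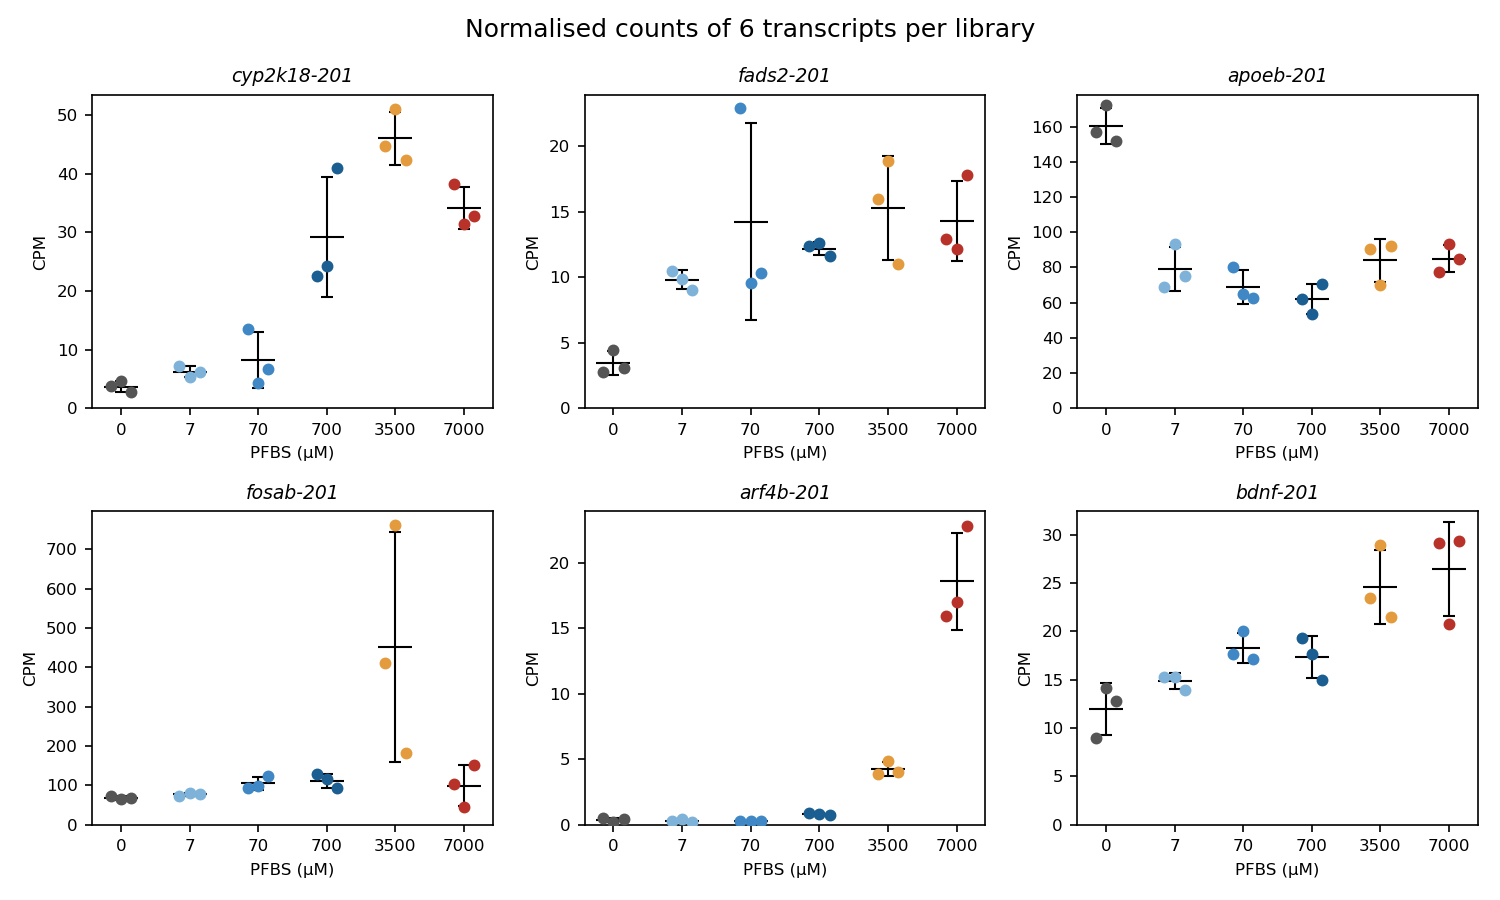
CPM of 6 transcripts in each library (y axis, from 0) against PFBS concentration in µM (x axis, evenly spaced groups, 0 for controls). Points are libraries and bars are mean ± SD of 3. The arf4b level is 15.9 to 22.8 CPM at 7000 µM and 0.2 to 0.486 CPM in controls, and fosab reaches 181 to 761 CPM at 3500 µM.

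Transcripts called at 2 concentrations mostly had the same sign. Of the 18 transcripts called at 70 µM, 15 were called in the same direction at 700 µM, 14 at 3500 µM and 16 at 7000 µM, where independent lists would share 0, 0.3 and 1.3. Of the 74 called at 700 µM, 48 were called in the same direction at 3500 µM and 66 at 7000 µM, against 1.2 and 5.3 for independent lists. The calls at 3500 and 7000 µM shared 616 transcripts in the same direction and 1 in the opposite direction, against 74.6 for independent lists. With 3 controls the comparisons could not be given separate sets of 2 control libraries, so the part of the excess that comes from the shared controls was not measured.

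The direct comparison of 7000 with 3500 µM called 245 transcripts higher and 320 lower at 7000 µM, and that of 3500 with 700 µM called 38 higher and 11 lower at 3500 µM. The following transcripts were chosen after their values were seen. The Golgi GTPase transcript arf4b was higher in both steps, with log2 differences of 2.4 from 700 to 3500 µM (adjusted p = 0.00229) and 2.13 from 3500 to 7000 µM (adjusted p = 0.00137). In the same steps btg2 differed by 1.81 and -2.04 (adjusted p = 0.0297 and 0.00525) and ier2b by 1.86 and -1.94 (adjusted p = 0.0388 and 0.0106). The transcript fosab differed by 2.01 (adjusted p = 0.0667) and -2.19 (adjusted p = 0.023). The uncoupling protein transcript ucp3 was lower at 7000 than at 3500 µM (-1.39, adjusted p = 0.0319), as were angptl4 (-0.82, adjusted p = 0.0128) and gfap (-1.19, adjusted p = 0.015). The count for 7000 against 3500 µM was 64 without 7000 µM replicate 3, 115 without 3500 µM replicate 1 and 304 without 7000 µM replicate 1. It was 334 and 353 without 3500 µM replicates 2 and 3. For 3500 against 700 µM the count was 4, 9 and 2 without 700 µM replicates 1, 2 and 3. It was 8 and 1042 without 3500 µM replicates 1 and 2, and 188 without 7000 µM replicate 3. With only the 2 groups compared in the fit, the counts for 7000 against 3500 µM and 3500 against 700 µM were 2 and 0. They were 13 and 8 with the notochord and epidermis mean as a covariate.

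Over the order of the 6 groups, 7093 transcripts had a trend, 3796 upward and 3297 downward. The sterol-regulated insig1 rose by 0.16 per step (adjusted p = 0.000585), hsp70l by 0.36 (adjusted p = 1.88e-05), cyp2k18 by 0.78 (adjusted p = 5.11e-05) and bdnf by 0.22 (adjusted p = 0.000144), values chosen from transcripts named above. The trend count was 1698, 4199 and 2478 without replicates 1, 2 and 3 of all groups, and 4879 without 7000 µM replicate 3.

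**Figure D5:**
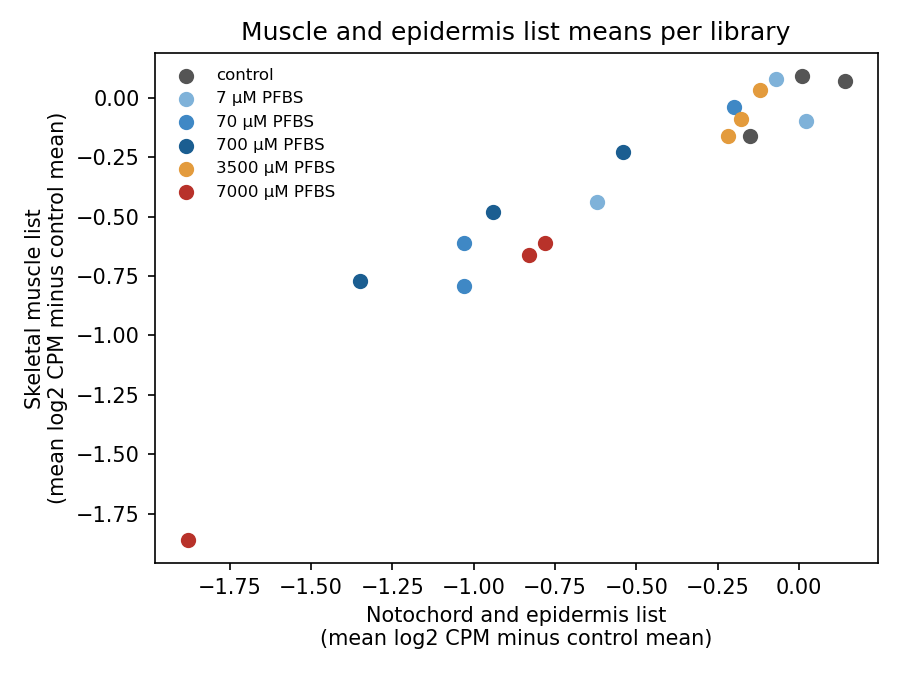
Mean log2 CPM minus the control mean of the skeletal muscle list (y axis) against that of the notochord and epidermis list (x axis) for each of the 18 libraries, coloured by PFBS concentration. Replicate 3 at 7000 µM lies lowest on both axes, at -1.86 and -1.88, and libraries of 70 and 700 µM reach -0.79 and -0.77 on the muscle axis.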

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

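The tests of the 3 patterns weighed here, and the counts of splits, were chosen after the results were seen, while the direct comparisons of concentrations were planned. Several gene lists differed between neighbouring concentrations in those direct comparisons (fry, adjusted over 42 lists). Cell cycle and DNA replication genes were lower at 7000 than at 3500 µM by a median log2 of -0.24 (adjusted p = 0.045; adjusted p = 0.39 with an estimated correlation), with 6 of 66 lower over all transcripts and 23 lower adjusted over the list alone. They were lower at 3500 than at 700 µM as well (median -0.16, adjusted p = 0.043; adjusted p = 0.32 with an estimated correlation), with 2 and 8 lower. Genes of p53 and apoptosis were higher at 3500 than at 700 µM (median 0.2, adjusted p = 0.0059; adjusted p = 0.088 with an estimated correlation), with 5 of 45 higher over all transcripts and 12 higher and 1 lower adjusted over the list alone. The unfolded protein and integrated stress response list (median 0.1) and the Nrf2 and oxidative stress list (median 0.14) were higher at 3500 than at 700 µM with adjusted p of 0.043 each, and 0.32 each with an estimated correlation.

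Skeletal muscle transcripts were low at 7000 µM, with a median log2 change of -0.96 over the list, and most so in replicate 3. With the trend on transcript length removed the median was -0.8 (interquartile range -1.11 to -0.42, lengths known for 90 of 90 transcripts), which argues against length bias as the whole cause. Without mitochondrial and ribosomal RNA the median was -0.96. TMM scaling already trims transcripts with extreme values, so leaving those RNAs out could hardly move the median. That fit does not decide whether those RNAs took counts. Within groups, the deviations of the muscle mean followed those of the notochord and epidermis mean over the 18 samples (Pearson r = 0.96, permutation p = 0.0011, 0.009 adjusted over 41 lists; Spearman rho = 0.95, permutation p = 0.00056, adjusted 0.0046; r = 0.94 without the 2 farthest samples). A share of body wall tissue that differed between samples is therefore a candidate explanation. The correlation was not particular to tissue markers. Heat shock (r = 0.81, permutation p = 0.0017, adjusted 0.012) and Nrf2 and oxidative stress (r = 0.71, permutation p = 0.00053, adjusted 0.0054) followed that mean too, while cholesterol synthesis did not (r = -0.03, permutation p = 0.88, adjusted 0.9). With the notochord and epidermis mean as a covariate the muscle median at 7000 µM was 0.01 (adjusted p = 0.97). The covariate itself was low in this group, at -0.83, -0.78 and -1.88. That fit would also remove an effect of PFBS on body wall genes, so it cannot tell these explanations apart. An effect of PFBS concentration stays open as well, since the muscle mean over the 15 exposed samples had r = -0.34 with log10 concentration (permutation p = 0.22, 0.33 adjusted over 6 relations; rho = -0.34, permutation p = 0.21, adjusted 0.32; r = -0.27 without the 2 farthest samples), and a lower RNA quality of replicate 3 was not tested.

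Cholesterol synthesis genes were high and neutrophil and macrophage genes low at all 5 concentrations, with medians of 0.49 to 0.62 and of -0.34 to -0.61. With the notochord and epidermis mean as a covariate the cholesterol median at 7 µM was 0.39 (adjusted p = 0.00041), which argues against the share of body wall tissue as its whole cause there. The neutrophil and macrophage median at 7 µM went from -0.4 to -0.25 (adjusted p = 0.0067). A single list mean may not take out all of that share, so this fit does not decide it for that list. Its call in the main fit was also lost with 5 of the 6 libraries left out in turn (adjusted p from 0.06 to 0.22). At 7000 µM the neutrophil and macrophage median went from -0.5 (adjusted p = 0.0052) to -0.08 (adjusted p = 0.55) with the covariate and the call ended because the median shrank. The covariate itself was low in this group, so that fit would also remove an effect of PFBS that moves with it. Within groups this list followed the notochord and epidermis mean (r = 0.78, permutation p = 0.0026, 0.013 adjusted over 41 lists, and rho = 0.83, permutation p = 0.0019, adjusted 0.011, with r = 0.78 without the 2 farthest samples). The share of body wall tissue is therefore a candidate explanation there, though lists other than tissue markers followed that mean too, and the covariate fit cannot decide it. Controls that differed from every exposed sample for a reason other than PFBS cannot be told apart from an effect of PFBS already complete at 7 µM, because all comparisons share the same 3 controls. The cholesterol mean of the 15 exposed samples had r = 0.46 with log10 concentration (permutation p = 0.082, 0.16 adjusted over 6 relations, and rho = 0.53, permutation p = 0.044, adjusted 0.088). The neutrophil and macrophage mean had r = -0.1 (permutation p = 0.73, adjusted 0.88, and rho = -0.16, permutation p = 0.57, adjusted 0.68). Without 2 of the 7 µM samples, the farthest in concentration, r was 0.33 and 0.08.

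At 7000 µM, 64 called transcripts had 0 counts in every library of 1 group, and 62 of them belonged to genes with several transcripts. Most of their genes as a whole did not go on or off, since 57 of the 64 gene sums changed by less than 2-fold. Where the called transcript was the only one of its gene, the gene sum was at 0 in that group too. Reads assigned to different transcripts of a gene in different libraries are a candidate explanation: among controls, 172 of 22826 tested transcripts of such genes (0.754%) were at 0 in 1 control and at 5 CPM or more in another, against 0 of 8895 transcripts of genes with a single transcript, which allows a share of up to 0.0337%. A real change of splicing in exposed larvae was not tested.

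Other splits of the samples were counted for each comparison. Each comparison of 3 against 3 samples has 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 0 and 0 at 7 µM (10 of 10 splits as large), 18 and 1 at 70 µM, 74 and 0 at 700 µM, 1039 and 1 at 3500 µM, 4510 and 2 at 7000 µM, 565 and 8 for 7000 against 3500 µM, and 49 and 2 for 3500 against 700 µM, with 1 split as large, the real one, in each of the latter. For the trend, 1 of 100 orders of the 18 samples, the real one, gave 7093 transcripts, and the highest other gave 205. For the gene lists 1 of 100 orders gave 52 calls and the highest other 20. For these counts a chance order of the samples is under a share of 0.05, provided that the 18 samples are independent. The labels do not show that they are. If samples of a group shared a pool, differences between pools would give such counts as well.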

How the results depend on the processing

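Leaving out 7000 µM replicate 3, the covariate, and for the gene lists the size factors and leaving out samples were chosen after seeing the data, and the other alternatives were planned. Relative log expression size factors kept every count within 1.5 times. Numbers are of calls, the causes were not tested unless stated, and with 3 samples per group the self-test missed part of the changes of a log2 of 1. Of the 192 calls of named genes, 191 kept their direction and call under relative log expression size factors and under DESeq2, 192 under a filter of 1 CPM, 170 with counts summed per gene, 159 without a filter, 149 with the replicate block, 103 with only the 2 groups compared in the fit and 85 with the epidermis list mean as a covariate. DESeq2 gave 75, 172, 795 and 2452 at 7, 70, 700 and 3500 µM, 1972 for 7000 against 3500 µM and 871 for 3500 against 700 µM. With counts summed per gene, which test fewer features, these were 7, 59, 674, 1994, 1321 and 350. A log2 fold change of at least 1, by construction lower, left 36, 327 and 1397 at 700, 3500 and 7000 µM and 230 and 23 for the direct comparisons. Without a filter the counts were 6, 26 and 627 at 70, 700 and 3500 µM and 316 and 31 for the direct comparisons, and with the filter of 1 CPM the last was 90. With only the 2 groups compared in the fit, which leaves fewer samples to estimate the spread, they were 0, 17, 154 and 1978 at 70, 700, 3500 and 7000 µM and 2 and 0 for the direct comparisons. With the epidermis list mean as a covariate they were 1, 4, 16, 1598 and 137 from 7 to 7000 µM and 13 and 8 for the direct comparisons. At 7000 µM that list itself then turned upward (fry adjusted p = 0.008), which is not read as a result because its own mean was the covariate. Gene lists called numbered 52 of 210 tests by fry, 23 by camera with an estimated correlation and 119 with the preset one. The overlap of 3500 and 7000 µM fell from 616 to 96 at an adjusted p under 0.01, and was 488 without 7000 µM replicate 3. With counts summed per gene, 5 named transcripts at 7000 µM had the opposite sign, because other transcripts of the gene were counted too: map1aa -0.2, myom2a (chromosome 11, 11200550 to 11262062) -1.41, ldha 0.35, ssr2 0.15 and hspd1 0.38. Leaving out 1 library gave 0 to 5 calls at 7 µM, 1 to 19 at 70, 6 to 241 at 700, 219 to 2806 at 3500 and 1588 to 4785 at 7000 µM, 64 to 691 and 2 to 1042 for the direct comparisons and 37 to 59 for the gene lists. The trend had 1698 to 4199 without 1 replicate number of all groups and 4879 without 7000 µM replicate 3. The lowest counts came without control replicate 1 (700 and 3500 µM and the gene lists), 70 µM replicate 1 (70 µM), 7000 µM replicate 3 (7000 and 7000 against 3500 µM), 700 µM replicate 3 (3500 against 700 µM) and replicate 1 of all groups (trend). The log10 concentration in the 15 exposed samples gave 5135 trends. A pseudocount did not apply to counts, and no fold threshold was applied to the trend.

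Replicate numbers did not pair the samples: deviations of samples with the same number correlated between -0.33 and 0.27 (mean -0.02, other numbers 0.01), and 3 of 18 libraries correlated best with their own number. With the replicate block the counts were 3 at 70 µM, 22 at 700 µM, 279 for 7000 against 3500 µM and 5 for 3500 against 700 µM, and the other counts stayed within 1.5 times (847 at 3500 µM, 3893 at 7000 µM, 6692 for the trend, 41 lists).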

Other observations

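Tests across concentrations in this part were chosen after the results were seen, and the gene lists were planned. Xenobiotic metabolism, with 77 measured genes, was not called at 7000 µM (median -0.12, fry adjusted p = 0.19), and its members went both ways: 4 were higher and 12 lower over all transcripts, with the same counts adjusted over the list alone. The following genes of the list were chosen after their values were seen. The cytochrome P450 transcript cyp2k18 stood at 34.2 ± 3.61 against 3.72 ± 0.942 CPM (n = 3 each, log2 fold change 3.2 ± 0.35, adjusted p = 0.00024) and cyp2aa4 was 1.8-fold higher, while the glutathione transferase gstr fell from 62.5 ± 8 to 27.4 ± 2.54 CPM (-1.19 ± 0.11, adjusted p = 9.6e-05) and the efflux transporter abcg2a was 2.41-fold lower. Amino acid catabolism and urea cycle genes had 6 higher and 16 lower of 60 (median -0.16, adjusted p = 0.12). Lens crystallins had 6 higher and 1 lower of 41 over all transcripts and 8 higher and 1 lower adjusted over the list alone (median 0.44, adjusted p = 0.19). Circadian clock genes had 13 higher and 1 lower of 45 at 7000 µM, and 14 higher and 2 lower adjusted over the list alone (median 0.18, adjusted p = 0.084).

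Over the 15 exposed samples, the hypoxia and glycolysis list mean rose with log10 concentration (Pearson r = 0.86, permutation p = 7e-05, 0.00042 adjusted over 6 relations; Spearman rho = 0.94, permutation p = 1e-05, the smallest that the resamples can give, adjusted 6e-05; r = 0.86 without the 2 farthest samples), by 0.08 per 10-fold. The phototransduction mean rose by 0.15 per 10-fold (r = 0.66, permutation p = 0.0064, adjusted 0.019; rho = 0.69, permutation p = 0.0063, adjusted 0.019; r = 0.57 without the 2 farthest samples). Fatty acid and triglyceride synthesis had r = 0.01 (permutation p = 0.97, adjusted 0.97, and rho = 0.08, permutation p = 0.77, adjusted 0.77), with r = 0.11 without those 2 samples. The phototransduction rise was not steady. Its list means were 0.63, 0.5 and 0.33 at 700 µM, 0.3, 0.15 and 0.36 at 3500 µM and 0.61, 0.46 and 1.01 at 7000 µM. The list was not called at 3500 µM (fry adjusted p = 0.14), where the notochord and epidermis means were near the controls (-0.12, -0.18 and -0.22). The slope was not adjusted for the notochord and epidermis mean. Within groups, the phototransduction mean went against the notochord and epidermis mean over the 18 samples (r = -0.87, permutation p = 0.0038, 0.016 adjusted over 41 lists; rho = -0.81, permutation p = 0.0053, adjusted 0.02; r = -0.78 without the 2 farthest samples). With that mean as a covariate the phototransduction median at 7000 µM was 0.33 (adjusted p = 0.052) and that of hypoxia and glycolysis 0.31 (adjusted p = 4e-07).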
